A study of Danio rerio with 57 samples.

How the data were processed

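H3K9me3, the trimethylation of lysine 9 on histone H3 that marks heterochromatin, was mapped in whole zebrafish embryos of the AB strain by CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA around the marked nucleosomes. Per the labels, the series holds 57 libraries. The time course has 17 H3K9me3 libraries and 10 IgG libraries, the IgG being a control antibody without a chromatin target. The H3K9me3 libraries number 2 at 2 h post fertilisation (hpf) and 3 at each of 2.5, 3, 3.5, 4 and 4.5 hpf. A further 27 H3K9me3 libraries made with antibodies from 3 suppliers and 3 IgG libraries form a confirmation experiment, of which 10 libraries were taken at 24 hpf. Only the time course is analysed here, because the 6 deposited lists are named for its time points. The confirmation experiment also has libraries at 2.5 and 4.5 hpf, so the names alone do not tie those lists to the time course. All libraries carried an E. coli DNA spike-in per the labels. How the spike-in was used is not given in the sources used here.

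The authors deposited one list of H3K9me3 regions per time point. The submitters' processing notes name Trim Galore, STAR, SAMtools, Picard, bedtools and HOMER without versions or roles. The lists do not say which libraries entered them or how replicates were combined. They were therefore treated as one pooled list per time point, with no value per replicate, and no spread between embryos can be given. The files have no header. By their values, the deposited columns hold the sequence name, start and end, a region name, a score, a signal, a p-value and a q-value. The deposited score followed the p-value: it equalled a multiple of the log2 of that p-value, capped at 1000, within 1 unit in every row of 5 lists and in 7504 of 7516 rows at 2 hpf. Regions at the cap share one score and differ only in the p-value. The unit and normalisation of the deposited signal are not given in the sources used here, so signal was compared between chromosomes within one list and not read as a level between time points. The deposited q-values fell below 0.05 for 4, 127, 257, 25, 4 and 0 regions from 2 to 4.5 hpf, so the lists were not filtered on them, and a q-value threshold was not used. The deposited p-value was under 0.05 for 8.43% to 13.3% of the regions of a list. What it tests, enrichment or repeatability between replicates, is not given in the sources used here. Region names begin with either primary or secondary, a distinction that no header explains. Regions named primary made up 31.4%, 18.0%, 21.2%, 29.2%, 31.3% and 14.1% of the successive lists and had the lower median p-value in each list. Read depth is unknown, so no counting interval or detection limit is given for a region, and a longer list can reflect deeper sequencing as well as more of the mark.

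The genome build is not given in the sources used here. Sequence names are 1 to 25 plus KN and KZ scaffolds, and the furthest region on chromosome 4 ends at 78.1 Mb. The gene table at hand is for another assembly, GRCz12tu, in which the furthest gene lies beyond the furthest region on 24 of 25 chromosomes. Its coordinates were not used. Gene lists, promoter, exon and intron shares, repeat shares and GC content had been planned before the data were examined and were not computed, so regions are named by position alone and no gene is named. The plan made the chromosome 4 and chromosome end comparisons depend on an annotation of the same build. That condition was not met, and both were made on the positions in the lists alone, with the arm boundary as planned. Positions are those of the lists, counted from 1. Chromosome lengths were taken as the furthest region end in any list, 1345 Mb in all.

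Regions of a list that touch were merged for all measures of covered length and overlap. A region was said to persist when at least 1 bp of it was covered in the next list. Length gained between consecutive lists was split into extension, meaning newly covered bases in a later region that overlaps an earlier one, and separate new regions. The merged union of all lists was dated by the earliest list that overlaps each union region. The long arm of chromosome 4 was set as everything from 28 Mb to the end and chromosome ends as the outer 1 Mb on each side. Chance placement was tested by rotating a list as one ring around the concatenated 25 chromosomes, 1000 times with a fixed seed. This permutation test is two-sided, its smallest p is 0.002, and p-values were adjusted by Benjamini-Hochberg within each family of 4 to 6 tests. It asks whether regions lie where chance would put them. It says nothing about variation between embryos. Intervals on the chromosome 4 ratio are 95% bootstrap intervals over 1 Mb windows, 2000 draws, and neighbouring windows are not independent. Scaffolds were counted in list sizes and left out of all overlap measures. The rule for named regions, fixed before the data were examined, took the 5 widest regions of the first and last lists.

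Alternatives planned before the data were examined were other overlap definitions, merging within 1 or 5 kb, a minimum width of 1 kb, the best scored 50% of each list, rotation within each chromosome, other starts of the chromosome 4 arm and leaving out each time point. Values without chromosomes 1 and 10 to 14, values from regions named primary only, equal list sizes, the length over 2 hpf regions found in every list and the tests of change in the chromosome 4 and chromosome end ratios were added after the data were seen. The split of gained length had been planned as a description beside its rotated value, and its p-values were added. The code was tested on simulated lists built from the step from 2 to 2.5 hpf (7233 regions): a planted persistence of 60.0% was returned as 60.5%, a planted extension share of 50% as 49.6%, and 5% of 100 unrelated pairs of lists fell below a p of 0.05. Planted new regions were kept clear of earlier ones, so the split was not tested for new regions lying close to earlier ones. The unrelated pairs were made by the same rotation that the test uses. The share of unrelated pairs therefore checks the code alone and cannot show whether rotation is a fair model of chance for real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.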

Results

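H3K9me3 was followed through the first hours of zebrafish development at 6 time points, 2, 2.5, 3, 3.5, 4 and 4.5 hpf, a window that runs from the end of the cleavage stages through the blastula stages, with the major wave of zygotic genome activation, to the start of epiboly, the spreading of the cell layer over the yolk. The series asks how the mark is first placed and then built up. One list of H3K9me3 regions per time point was analysed. The lists were taken to come from the time course, with 2 H3K9me3 libraries at 2 hpf and 3 at each later time point. They do not state which libraries entered them. The lists held 7516, 21196, 32756, 43657, 51200 and 33704 regions in order of time. Because each time point is a single pooled list, differences between time points have no replicate check, and the depth behind a region is unknown. The IgG libraries were not analysed here, so no background value stands beside the lists.

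H3K9me3 regions were few and narrow at 2 hpf and covered a growing part of the genome up to 4 hpf. At 2 hpf the regions covered 6.52 Mb in all, scaffolds included, and 0.468% of the 25 chromosomes. At 4 hpf they covered 93.3 Mb in all and 6.68% of the chromosomes, a 14.3-fold rise in covered length against a 6.81-fold rise in the number of regions. Both rises were steeper among regions at least 1 kb wide, which numbered 1823 at 2 hpf and 26579 at 4 hpf and covered 3.21 Mb and 77.7 Mb. Regions named primary numbered 2361 and 16037 and covered 3.46 Mb and 36.4 Mb, a smaller rise in length. The steepest step was the first one, from 2 to 2.5 hpf, with a 3.53-fold rise in covered length. It is also the only step at which the number of H3K9me3 libraries in the time course changes, from 2 to 3. With read depth unknown, the lists cannot separate the 2. The following steps to 3, 3.5 and 4 hpf gave 2.01-fold, 1.60-fold and 1.26-fold. Over all regions of a list, the median width was 630 bp at 2 hpf, 829 bp at 3 hpf and 1044 bp at 4 hpf. Among regions named primary it was 1250 bp, 2317 bp and 1988 bp. Regions of at least 5 kb increased from 21 at 2 hpf to 3675 at 4 hpf. At 4.5 hpf the list was shorter, 0.658 times that at 4 hpf, its covered length was 90.9 Mb and its median width was 1713 bp. Regions named primary covered 36.4 Mb at 4 hpf and 14.3 Mb at 4.5 hpf.

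**Figure D1:**
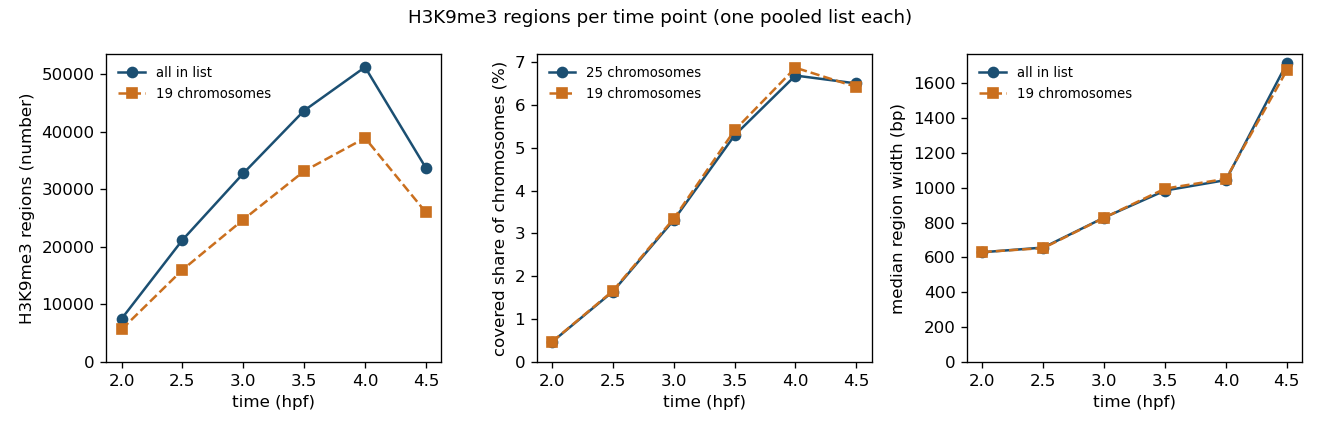
Number of H3K9me3 regions, share of the chromosomes covered (%) and median region width (bp) against time (hpf), for all sequences or all 25 chromosomes (circles) and for the 19 chromosomes other than 1 and 10 to 14 (squares). Each point is one pooled list, so there are no error bars. Covered share rises from 0.468% at 2 hpf to 6.68% at 4 hpf, and median width is largest at 4.5 hpf.

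The 4.5 hpf list was not uniform across chromosomes. On chromosomes 1, 10, 11, 12 and 13 the median region signal lay between 562.5 and 731, against 102 to 192 on the 19 chromosomes from 15 to 25 and 2 to 9. At 4 hpf the ratio of the medians of these sets was 0.954, and at 4.5 hpf it was 5.09. Chromosome 14 split at position 13515416. Before that point it held 445 regions with a median signal of 779, and in the remaining 39.1 Mb it held 8 regions, where the 4 hpf list had 1148. Covered share rose from 4 to 4.5 hpf on all 5 of chromosomes 1 and 10 to 13, with a median ratio of 1.26. It fell on all 18 of the others besides chromosomes 4 and 14, with a median ratio of 0.912. Values for the 19 chromosomes outside this set are therefore given beside the main 4.5 hpf values. On those 19 chromosomes covered share was 6.86% at 4 hpf and 6.41% at 4.5 hpf, and median width was 1051 bp and 1673 bp.

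**Figure D2:**
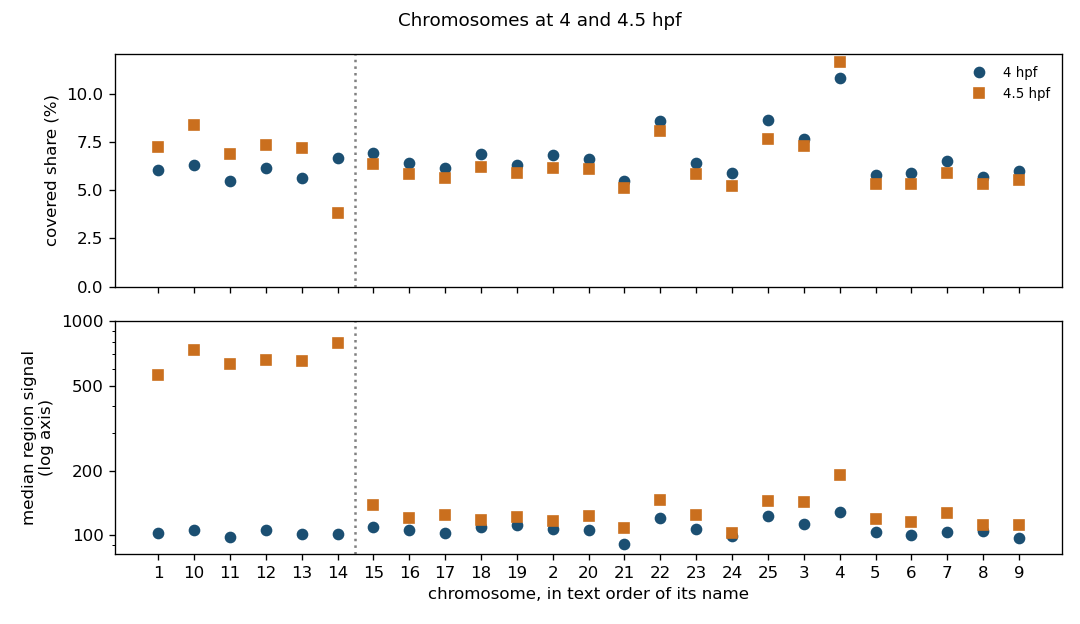
Covered share (%) and median region signal (log axis, unit not given) of each chromosome at 4 hpf (circles) and 4.5 hpf (squares), with chromosomes in the text order of their names. The dotted line follows chromosome 14. Signal at 4.5 hpf is 562.5 or above on the chromosomes left of the line and 192 or below on those right of it.

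Most regions seen at one time point were seen again at the next. Of the 7233 chromosomal regions at 2 hpf, 59.8% overlapped a region at 2.5 hpf, against 2.83% on average when the later list was rotated. Persistence was 67.8% from 2.5 to 3 hpf, 75.3% from 3 to 3.5 hpf and 83.5% from 3.5 to 4 hpf, against rotation means of 5.54%, 9.11% and 12%. From 4 to 4.5 hpf it was 59.5%, against 10.5%, and 60.6% on the 19 chromosomes. All 5 steps exceeded every rotation (permutation test, adjusted p = 0.002, the smallest that 1000 rotations can give). Regions that persisted had the larger median width in each step. On the 19 chromosomes, regions at 2 hpf that persisted had a median width of 787 bp and those that did not had 500 bp. From 3.5 to 4 hpf the corresponding medians were 1184 bp and 500 bp. When only regions named primary entered both lists, persistence from 4 to 4.5 hpf was 24.9%.

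Over all listed regions, the length gained between consecutive time points lay mostly in separate new regions in the first step. In the last 3 steps it lay mostly in regions overlapping earlier ones, by a narrow margin from 3 to 3.5 hpf. From 2 to 2.5 hpf, 18.2 Mb were gained, of which 27.6% lay in regions overlapping an earlier region and 72.4% in new ones. Extension made up 45.8% of the gain from 2.5 to 3 hpf, 50.8% from 3 to 3.5 hpf, 57.3% from 3.5 to 4 hpf and 73.1% from 4 to 4.5 hpf. The last value was 69.4% on the 19 chromosomes. Rotated later lists gave 1.33%, 4.64%, 7.70%, 11.4% and 17.2%, so that part of the increase accompanies the growth of the lists themselves, and each observed share lay above its rotations (permutation test, adjusted p = 0.002, the smallest possible). The order of the steps and the larger part of the gain depended on the regions counted. With regions named primary alone, extension shares were 35.6%, 29.6%, 15.3%, 25.7% and 42.6%, without a steady rise. New regions then held most of the gain in every step. When later regions within 5 kb of an earlier one counted as extension, its share was 42.3% from 2 to 2.5 hpf and 61.8% from 2.5 to 3 hpf. Length no longer covered was 2.34 Mb in the first step and 24.5 Mb in the last, or 18.5 Mb on the 19 chromosomes. The earlier list covered 6.29 Mb of the chromosomes at 2 hpf and 89.85 Mb at 4 hpf, so the share lost was larger in the first step.

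**Figure D3:**
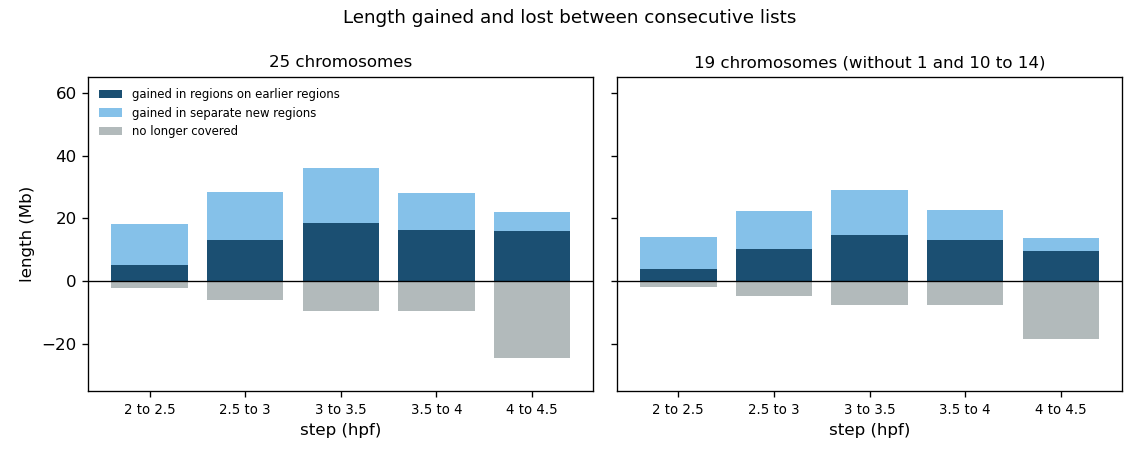
Length (Mb) gained in regions that overlap an earlier region (dark), gained in separate new regions (light) and no longer covered (grey, below 0) for each step between consecutive lists (hpf), on 25 chromosomes and on the 19 other than 1 and 10 to 14. New regions make up 72.4% of the first gain. The lost length in Mb is largest in the step from 4 to 4.5 hpf, where the earlier list also covers the most.

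Of the regions at 2 hpf, 3063 were found in every later list. Their median width was 865 bp at 2 hpf, and the later regions lying over them had a median total length of 2037 bp at 2.5 hpf, 3445 bp at 3 hpf, 4584 bp at 3.5 hpf and 5274 bp at 4 hpf. At 4.5 hpf the value was 5499 bp over all chromosomes and 5188 bp on the 19 chromosomes, against 5272 bp at 4 hpf on the latter. These places were chosen for being found throughout, and the later values sum whole regions over each place, which favours long regions, so part of the increase is built into the measure. No value under rotation was computed for it. The 5 widest regions at 2 hpf differed in the length that later lay over them. The region at chromosome 10, 2467002 to 2473683, was 6682 bp long, and the regions over it reached 17078 bp at 2.5 hpf and 25860 bp at 4 hpf. The region at chromosome 3, 2900071 to 2907357, was 7287 bp long and was overlaid by 30810 bp at 4 hpf. At chromosome 6, 20839977 to 20846425, the overlapping length was 6449 bp at 2 hpf and 9730 bp at 4 hpf. At chromosome 13, 7307733 to 7314074, it was 6342 bp at 2 hpf and 9211 bp at 4 hpf. At chromosome 15, 10782876 to 10789629, it was 6754 bp at 2 hpf, 16134 bp at 2.5 hpf and 8982 bp at 4 hpf. At 4.5 hpf the length was 23122 bp at chromosome 3, 9918 bp at chromosome 6 and 9166 bp at chromosome 15. On chromosomes 10 and 13, which stand apart in that list, it was 26896 bp and 13680 bp.

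**Figure D4:**
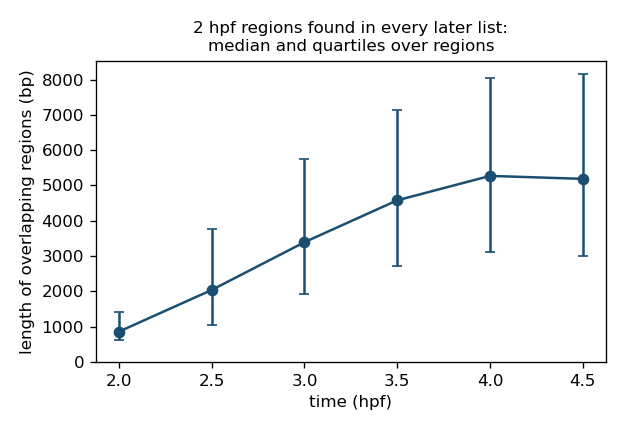
Total length (bp) of the regions that lie over each 2 hpf region found in every later list, against time (hpf), on the 19 chromosomes other than 1 and 10 to 14. Points are medians over 2466 regions, and bars run from the lower to the upper quartile over regions, which are not replicates. The median rises from 862 bp at 2 hpf to 5272 bp at 4 hpf and is 5188 bp at 4.5 hpf.

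The 5 widest regions at 4.5 hpf lay on chromosomes 1, 4, 11, 13 and 14, and 57 of the 100 widest regions lay on the 6 chromosomes that stand apart in this list. The widest, at chromosome 1, 28231454 to 28332648, spanned 101 kb, and regions covered 7.82% of it at 2 hpf, 40.1% at 3 hpf and 81.2% at 4 hpf. Outside those 6 chromosomes the widest region was at chromosome 4, 28726435 to 28804125, 77.7 kb long, with 2.07% covered at 2 hpf, 39.8% at 3 hpf and 96.2% at 4 hpf. A 53.1 kb region at chromosome 22, 3516955 to 3570038, was covered over 16.8% at 2 hpf and 98.2% at 4 hpf. A 43.9 kb region at chromosome 6, 18003501 to 18047370, was covered over 1.39% at 2 hpf and 86.8% at 4 hpf. A 43.4 kb region at chromosome 2, 12770399 to 12813775, went from 8.61% to 97.7%, and a 35.1 kb region at chromosome 8, 38967212 to 39002354, from 8.02% to 94.0%. The other 3 of the 5 widest were at chromosome 14, 12847329 to 12933698 (86.4 kb), chromosome 13, 19170427 to 19247289 (76.9 kb) and chromosome 11, 17846625 to 17907600 (61.0 kb), with 70.1%, 66.0% and 85.7% covered at 4 hpf. The authors' p-values of these wide regions were 0.956 to 0.972, and none was named primary. What these p-values measure is not given in the sources used here. All of these were picked for their width at 4.5 hpf, so lower coverage in other lists follows in part from the choice. The regions on chromosomes 22, 6, 2 and 8 were chosen after the values had been seen, by the same rule outside the 6 chromosomes.

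All 6 lists together formed 62659 union regions, of which 3311 (5.28%) were found in every list. The number first seen at each time point was 6371 at 2 hpf, 12079 at 2.5 hpf, 13740 at 3 hpf, 14735 at 3.5 hpf, 11523 at 4 hpf and 4211 at 4.5 hpf. Of the places first seen at 2, 2.5, 3, 3.5 and 4 hpf, 65.3%, 57.1%, 43.9%, 43.1% and 32.5% were present at 4.5 hpf, and on the 19 chromosomes 66.8%, 59.1%, 45.6%, 44.0% and 33.0%. Of those first seen at 2 hpf, 52.0% were in every later list and 15% were in the 2 hpf list alone. The median union width was 3390 bp for places first seen at 2 hpf, 1907 bp at 2.5 hpf, 1181 bp at 3 hpf, 916 bp at 3.5 hpf, 637 bp at 4 hpf and 754 bp at 4.5 hpf. A union region takes its width from all lists that overlap it, so places seen in more lists are wider by construction, and no test between these cohorts was made. A wide 4.5 hpf region that touches a 2 hpf region dates the whole place to 2 hpf and counts it as present at 4.5 hpf. Part of the higher share of early places present at 4.5 hpf is therefore built in too.

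Chromosome 4 ranked behind chromosomes 22, 25 and 3 at 2 hpf, with 0.560% covered, and ahead of all others at 4 hpf, with 10.8%. Its long arm is known to be heterochromatic and repeat-rich. From 28 Mb onward, covered share was 0.745% at 2 hpf, 4.81% at 3 hpf, 10.1% at 3.5 hpf, 15.1% at 4 hpf and 16.5% at 4.5 hpf. The part of chromosome 4 before 28 Mb was covered over 0.230% at 2 hpf and 3.18% at 4 hpf, below the rest of the genome, although its window from 26000001 to 27000000 reached 23.2% at 4 hpf. The ratio of the arm to the rest was 1.63 (95% window interval 1.22 to 2.22) at 2 hpf, 1.55 (1.23 to 1.96) at 2.5 hpf and 1.48 (1.19 to 1.82) at 3 hpf. It was 1.98 (1.70 to 2.31) at 3.5 hpf, 2.37 (2.1 to 2.65) at 4 hpf and 2.71 (2.45 to 2.98) at 4.5 hpf, or 2.80 at 4.5 hpf on the 19 chromosomes. The share of all chromosomal regions that lay on the arm was 6.33% at 2 hpf and 6.04% at 4 hpf, while their median width went from 604 bp to 1412 bp. The corresponding medians on the rest of the 19 chromosomes were 633 bp and 1036 bp. At 4.5 hpf 26.1% of arm regions were at least 5 kb wide, against 11.4% of regions on the rest of the 19 chromosomes.

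By rotation, the arm ratio gave adjusted p-values of 0.045, 0.04995, 0.04995, 0.032, 0.024 and 0.024 from 2 to 4.5 hpf (permutation test). The values at 2.5 and 3 hpf lie at the threshold of 0.05. With 1000 rotations, another random seed could turn those calls. All 6 time points also passed with the arm taken from 25 Mb (adjusted p 0.018 to 0.032) or 30 Mb (0.024 to 0.048). With equal list sizes, the 7233 best scored regions of each list, 3.5, 4 and 4.5 hpf passed (adjusted p 0.045 at each). There 2.5 and 3 hpf did not pass (0.156 and 0.238). At 2 hpf these 7233 are all chromosomal regions, so its value (0.045) repeats the main result. No time point passed without chromosomes 1 and 10 to 14 (ratios 1.47 to 2.80, adjusted p 0.0539 to 0.0919), with the best scored 50% of each list (1.36 to 2.02, 0.0519 to 0.114) or with regions named primary (1.22 to 2.1, 0.0519 to 0.304). Without those chromosomes the ratio itself changed little, from 2.37 to 2.34 at 4 hpf. On the shorter ring, rotations that overlap the arm are a larger share of all rotations. The higher p therefore does not by itself show that the arm ratio depends on those chromosomes. How much of the rise in p comes from the shorter ring was not tested. The change in the ratio from 3 to 4 hpf, 1.60-fold with a 95% window interval of 1.42 to 1.82, did not pass (permutation p = 0.044, adjusted p = 0.0879). The ratio was lowest at 3 hpf. From 2 to 4 hpf the change was 1.45-fold (1.16 to 1.84), which was not tested by rotation.

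**Figure D5:**
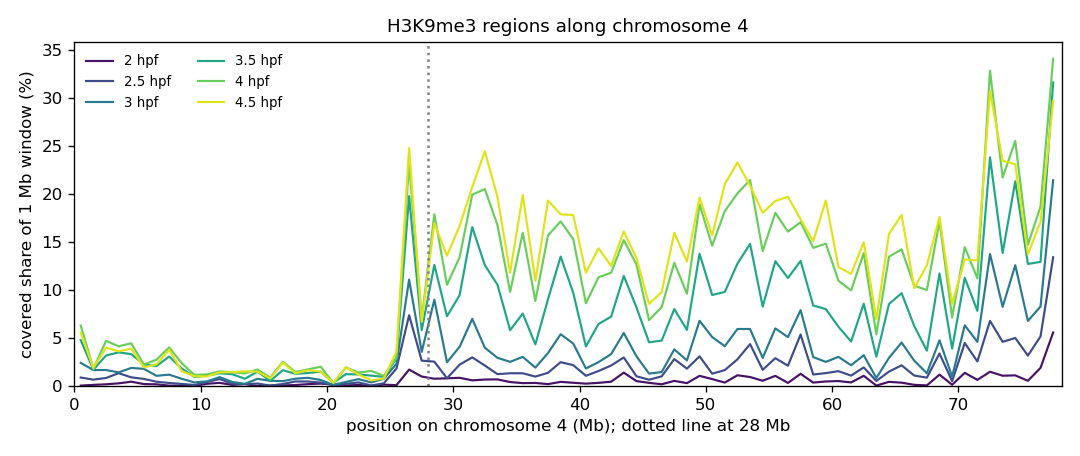
Share of each 1 Mb window of chromosome 4 covered by H3K9me3 regions (%) against position (Mb), one line per time point (hpf), with a dotted line at 28 Mb. At 4 hpf the window from 26000001 to 27000000, before the line, is covered over 23.2%, and the most covered window, from 77000001 to 78000000, over 34%.

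Chromosome ends carried more of the mark than interiors at every time point. The outer 1 Mb of the chromosomes was covered over 1.06% at 2 hpf, 8.90% at 3 hpf and 14.1% at 4 hpf, against 0.445%, 3.10% and 6.40% of the interior. The ratio was 2.38 at 2 hpf, 2.72 at 2.5 hpf, 2.88 at 3 hpf, 2.43 at 3.5 hpf, 2.20 at 4 hpf and 2.02 at 4.5 hpf (permutation test by rotation, adjusted p = 0.002 at each, the smallest possible). On the 19 chromosomes it was 3.05 at 3 hpf and 2.09 at 4.5 hpf. From 3 to 4 hpf the ratio fell to 0.765 times its value (permutation test, adjusted p = 0.00799), and to 0.762 times on the 19 chromosomes (adjusted p = 0.016). The ratio was highest at 3 hpf, and the lists grew from 32756 to 51200 regions over this step. Equal list sizes and the best scored 50% were not run for chromosome ends, so the part of list growth in this fall is unknown. The change from 2 to 3 hpf, 1.21-fold, did not pass (permutation test, adjusted p = 0.194).

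Among the other chromosomes, 22 and 25 were the most covered at 2 hpf, with 0.696% and 0.671%, and followed chromosome 4 at 4 hpf, with 8.58% and 8.66%. Chromosome 21 was lowest at 2 hpf, with 0.316%, and chromosome 11 was lowest at 4 hpf, with 5.48%. The most covered 1 Mb window at both 2 and 4 hpf was the one from 77000001 to 78000000 on chromosome 4, covered over 5.57% and 34%. The next at 2 hpf was chromosome 2, 14000001 to 15000000, with 4.95% at 2 hpf and 30.6% at 4 hpf. Of the 50 most covered windows, 2 lay on the chromosome 4 arm at 2 hpf and 8 at 4 hpf, where the arm holds 3.74% of all windows.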

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

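No test was made for this part. Regions on unplaced scaffolds, which no overlap comparison used, numbered 283 at 2 hpf, 831 at 2.5 hpf, 1193 at 3 hpf, 1540 at 3.5 hpf, 1808 at 4 hpf and 1367 at 4.5 hpf. They are listed because each number is above the 3 that a count of 0 allows and no control list was analysed here. They made up 3.77% of the list at 2 hpf and 4.06% at 4.5 hpf, on 182 and 541 scaffolds.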

How the results depend on the processing

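The tests without chromosomes 1 and 10 to 14, with regions named primary, with equal list sizes and of the change in the chromosome 4 and end ratios were chosen only after the data were seen. Of 215 values under alternative settings, 172 kept their direction and side of the threshold or stayed within 1.5 times, 20 kept their direction but lost significance, 23 moved and none reversed. Persistence, extension against rotation and the chromosome end ratio kept their call in every setting run for them, although with regions named primary the extension share no longer rose from step to step. New regions then held most of the gain in every step. The call for extension compares it with rotation and not with the part gained in new regions. For the chromosome end ratio, the only other settings were leaving out chromosomes 1 and 10 to 14 and keeping regions named primary alone. A minimum width of 1 kb left 1823, 6490, 13711, 21581 and 26579 regions from 2 to 4 hpf and 3.21 and 14.5 Mb at 2 and 2.5 hpf. Regions named primary numbered 2361, 3820, 6935, 12759, 16037 and 4751 from 2 to 4.5 hpf and covered 3.46, 9.09, 19.8, 32.3, 36.4 and 14.3 Mb. Leaving out the list before it raised the union regions first seen at 3, 3.5, 4 and 4.5 hpf to 21583, 23358, 22254 and 8096, by construction. The chromosome 4 arm lost its call in every time point with the best scored 50% of each list (ratios 1.5, 1.40, 1.36, 1.94, 2.02 and 2.00, adjusted p 0.0519 to 0.114), without chromosomes 1 and 10 to 14 (1.62, 1.54, 1.47, 1.96, 2.34 and 2.80, adjusted p 0.0539 to 0.0919) and with regions named primary (1.31, 1.27, 1.22, 1.98, 2.1 and 2.05, adjusted p 0.0519 to 0.304). With equal list sizes it lost it at 2.5 and 3 hpf (1.36 and 1.24). Over all chromosomes the ratios were 1.63, 1.55, 1.48, 1.98, 2.37 and 2.71. The cause of the lost calls was not tested. The soft-masked, annotation and gene list alternatives were not run, since no genome or annotation of the build was at hand. No paired analysis was possible because each time point is one pooled list without values per replicate, and no replicate could be left out for the same reason. Read depth is unknown, which limits every comparison of list sizes between time points.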

Other observations

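All tests in this part were chosen only after the lists had been examined, and those on the 4.5 hpf chromosomes and on the fall from 4 to 4.5 hpf after the values they measure had been seen. Most new H3K9me3 regions lay more than 5 kb from places already marked, but more of them lay within 5 kb than after local shifts. On the 19 chromosomes, 16.6% of the 11873 new regions at 2.5 hpf lay within 5 kb of a 2 hpf region, against 8.39% after shifts of 20 to 200 kb either way and 4.75% after rotation. The shares in the later steps were 26.1%, 31.6%, 39.0% and 44.3%, against shifted means of 16.6%, 22.9%, 29.0% and 32.8%, and the smallest ratio over the 5 steps was 1.34. One hypothesis is that the mark may spread in short jumps around earlier places. Wide domains that the region caller broke into pieces would give the same excess, and the lists do not separate these. A further 2 hpf pattern concerns which regions were seen again. In the narrowest quartile of 2 hpf regions, 34% (95% exact binomial interval 31.8% to 36.2%) overlapped a 2.5 hpf region, and in the widest 87.7% (86.1% to 89.1%), a difference of 53.7 percentage points. The intervals treat regions as independent, which neighbouring regions are not, and the first quartile ends among regions of exactly 500 bp (1227 in the list), whose ties were split by their order in the list, which follows the p-value. By 4 hpf the shares were 61.9% and 91.6%, so many narrow regions absent at 2.5 hpf were listed again later. A wider region also has more bases that can overlap by chance, so its share is expected to be somewhat higher.

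The first pattern for a second look is the 4.5 hpf list on chromosomes 1 and 10 to 14. The 5 whole chromosomes of highest signal were exactly the first 5 of 24 in the text order of their names, and the next name in that order, 14, broke within the chromosome. A difference in depth between whole libraries would raise all chromosomes alike, and the signal ratio of 5.09 at 4.5 hpf argues against it. A change of the mark in the embryo was not decided. Past the break on chromosome 14, 0.784% of the 4 hpf regions overlapped a 4.5 hpf region, against 60.6% on the 19 chromosomes. The break was read from the same 4.5 hpf list, so this low share restates the observation and is no test. A difference in how sequences were treated in the text order of their names may be the source and stays open: the chance of such an order at random, 2.35e-05, restates the observation that prompted the explanation and is no test of it.

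The second pattern is the fall in covered share from 4 to 4.5 hpf outside those chromosomes, a median ratio of 0.912 on 18 chromosomes with a range of 0.884 to 0.953, beside a rise of chromosome 4 to 1.08 times. If fewer libraries reached those chromosomes in the 4.5 hpf list, fewer narrow regions could pass into it, and a shift in the embryo toward fewer, wider domains would give the same values. These explanations cannot be told apart here, because no chromosome of the list is known to be free of such a difference in treatment.

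The third pattern is the ratio of the chromosome 4 long arm to the rest, 1.60 times as high at 4 as at 3 hpf, a change that did not pass (permutation test, adjusted p = 0.0879, and 0.12 on the 19 chromosomes). The 3 hpf ratio was the lowest of all time points, and the step was chosen after the data were seen. Against 2 hpf the ratio at 4 hpf was 1.45 times as high (95% window interval 1.16 to 1.84), which was not tested by rotation. The number of regions called is argued against as the whole cause: with 7233 best scored regions in each list, the ratio at 4 hpf was 2.17, 1.74 times that at 3 hpf (95% window interval 1.42 to 2.23). It was 1.33 times that at 2 hpf (1.03 to 1.72), where those 7233 are all chromosomal regions of the list. Equal numbers leave the widths as they are. The arm held 5.79% of chromosomal regions at 3 hpf and 6.04% at 4 hpf, while their median width went from 755.5 bp to 1412 bp. On the rest of the 19 chromosomes the median width went from 834 bp to 1036 bp. Widening of regions with deeper sequencing is not addressed by this cut and stays open, since read depth is unknown. A few windows of high coverage are argued against too, since without the 5 most covered arm windows the ratio was 2.18, and 1.78 times (1.62 to 1.96) that at 3 hpf with the same windows left out. The value against 2 hpf was 1.65 times (1.42 to 1.95). Reads shared between near-identical repeats on the arm stay open, since 0 columns of the lists count multiply mapped reads. Chance placement and a change with developmental time stay open too.

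Covered share showed no relation to chromosome length that passed correction over the 6 time points. Across the 25 chromosomes at 2 hpf Pearson's r was -0.16 (permutation p = 0.453, adjusted p = 0.543) and Spearman's rho -0.14 (permutation p = 0.493, adjusted p = 0.978), in a family of 6 time points. Over all chromosomes r was -0.18 at 2.5 hpf, -0.31 at 3 hpf, 0.01 at 3.5 hpf and 0.19 at 4 hpf. At 4.5 hpf it was 0.26 over 19 chromosomes. The 2 chromosomes farthest from the median length were 4 and 7, and chromosome 4 was the most covered at 4 hpf. Without them r was negative at all 6 time points, from -0.33 to -0.44, the 4.5 hpf value over 17 chromosomes. The negative sign of r at 3.5, 4 and 4.5 hpf therefore depends on leaving them out. Without these 2 chromosomes the unadjusted permutation p of r was 0.0361 at 3 hpf (r -0.44) and above 0.05 at the other 5, with 0.0689 at 2 hpf (r -0.39), and these were not corrected. Spearman's rho for the same chromosomes was -0.11 to -0.32, and its permutation p was 0.137 or higher at each time point.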
